A study of Homo sapiens with 2 samples.

How the data were processed

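JunB was immunoprecipitated from MCF7 cells after 7 days in 500 nM abemaciclib or DMSO, with 1 library per group. The sample titles add a number to the name of the line, and whether it marks a replicate, a subline or a batch is not given in the sources used here. Per the labels' protocols, chromatin was fixed with 2 mM DSG for 45 min and then 1% formaldehyde for 10 min, sonicated for 20 min, and 30 µg of it was precipitated with 3.1 µg of antibody. Per the submitters' processing notes, BWA and MACS2 were used with the hg19 genome. Their versions, the control used for peak calling, the read filters and the parameters are not given in the sources used here. The deposited lists hold 1 set of peaks per library, so peaks were called on each library separately.

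Each deposited peak has a position in hg19 and a summit. The authors' fold enrichment is a ratio of the pileup at the summit to the caller's local background. The authors' p-value and q-value columns are on the −log10 scale, with a lowest −log10 q of 1.31 in the DMSO list and 1.34 in the abemaciclib list. The deposited score was the whole part of 10 times the −log10 q in 100% of the peaks. These values depend on depth and on the control. They were used to describe, rank and filter peaks within each list, and the same q threshold in both lists is not an equal stringency. Pileups recovered from them were compared between the libraries only after division by each list's background floor. All positions are printed counting from 1. No intervals overlapped within a list, and no peak extended beyond the hg19 chromosome lengths. The abemaciclib list held 1 peak on the Y chromosome.

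Peaks were compared with bedtools 2.31.1, and an overlap of at least 1 bp counted as shared. Chance overlap was estimated by placing the abemaciclib peaks at random on their own chromosomes in 100 shuffles. Chromosome lengths came from GenomeInfoDb 1.38.1 and cytobands of hg19 from circlize 0.4.16, with each peak placed by its summit. Analyses were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Shares have exact Clopper-Pearson 95% intervals. They cover counting error only, since reads and neighbouring peaks are not independent and a second culture was not measured in either group.

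The number of reads at each summit and the background were recovered from the authors' fold and −log10 p. The caller's fold was taken as the pileup plus 1 over the background plus 1, and its p-value as a Poisson tail. In both lists 100% of the peaks matched a whole-number pileup within 0.002 on the −log10 p scale. On simulated data, 100% of 2000 pileups were recovered exactly, while 1.7% of randomly shifted p-values found a match within that tolerance. The overlap step found 1000 of 1000 planted overlaps and called 0 of 500 distant intervals shared. The median pileup at the summit was 23 reads in the DMSO list and 20 reads in the abemaciclib list. The lowest background of each list, its floor, served as a measure of relative depth, and its ratio between the libraries was 1.22. Divided by the shortest peak length, which differed between the lists (302 and 295 bp), the ratio was 1.25.

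The peaks named in the report follow a rule fixed before the data were examined. It takes the 10 abemaciclib-only and 5 DMSO-only peaks of highest fold, and the 5 shared peaks with the best mean rank by fold, at a −log10 q of at least 5 on assembled chromosomes. Peaks named in the closing section were chosen after their values were seen. Alternatives fixed at the same time were stricter thresholds (−log10 q of at least 5 or 10), other definitions of a shared peak, lists of equal length, merged intervals, chromosomes 1 to 22 and X only, −log10 p in place of fold, and covered length in place of peak number. Thinning by the ratio of the background floors, alone or with a raised background, leaving out bands of high background and leaving out chromosome ends were added after seeing the data, as was the choice of the arms 1q, 17q and 20q. Planned results on promoter, exon and intron location, on 13 binding motifs and on 16 gene lists were not run, because they need sequence or gene positions of hg19, which were not used here.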

Results

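JunB binding was mapped by ChIP-seq (chromatin immunoprecipitation followed by sequencing) in MCF7 cells, an established estrogen receptor-positive breast carcinoma line. JunB is a subunit of AP-1, a family of dimeric transcription factors. Cells had been kept for 7 days in 500 nM abemaciclib, an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6, or in an equal volume of DMSO, its solvent. Each group has 1 library, so no difference below has a replicate check and no p-value for a difference between the conditions is given. The DMSO list held 3549 peaks and the abemaciclib list 9234 peaks. Read totals are not used here. The lowest background value recovered from the authors' peak statistics, which scales with sequencing depth, was 1.51 reads in the DMSO list and 1.84 reads in the abemaciclib list, a ratio of 1.22. Fold enrichments and q-values are those of the authors' peak caller and are used to describe, rank and filter peaks within each list. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only.

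The question posed by the design was how JunB binding in MCF7 cells differed after abemaciclib. The abemaciclib list held 2.60 times as many JunB peaks as the DMSO list. Its peaks covered 4976 kb of the genome, or 0.161% of hg19, against 1901 kb, or 0.0614%, in the DMSO list. Peak widths were alike, with a median of 474 bp in the DMSO list and 468 bp in the abemaciclib list. The median fold enrichment was 5.98 (quartiles 4.65 and 8.45) in the DMSO list and 5.57 (quartiles 4.31 and 7.76) in the abemaciclib list. At a −log10 q of at least 5, 2781 DMSO peaks and 6628 abemaciclib peaks were left, a ratio of 2.38.

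Most JunB sites of the DMSO library were also occupied in the abemaciclib library. Of the DMSO peaks, 2889 (81.4%, interval 80.1 to 82.7%) overlapped an abemaciclib peak by at least 1 bp. These met 2874 abemaciclib peaks, which were 31.1% (30.2 to 32.1%) of that list. The other 6360 abemaciclib peaks had no overlapping DMSO peak, while 660 DMSO peaks had no overlapping abemaciclib peak, a ratio of 9.64. After thinning the abemaciclib pileups and backgrounds by the ratio of the background floors, and raising the background over the floor by the factor seen at shared sites, a median of 5279 abemaciclib-only and 733 DMSO-only peaks were left, a ratio of 7.19. Under that setting, 3704 (58.2%) of the abemaciclib-only peaks passed in at least 95 of 100 thinnings. The thinned pileups had been selected for passing in their own library. The raised background came from shared sites only, and the DMSO background at abemaciclib-only sites is not known. Abemaciclib peaks moved to random positions on their own chromosomes met 12.8 ± 3.65 DMSO peaks (SD over 100 shuffles), so that the observed overlap was 225 times that value. Those random positions ignored gene density and unmappable sequence. Summits of overlapping peaks lay a median of 40 bp apart (quartiles 17 and 80 bp), and 81.7% of the pairs had summits within 100 bp. With the abemaciclib list shortened to its 3549 strongest peaks by −log10 p, 62.0% of the DMSO peaks overlapped it and 1365 abemaciclib peaks were left unshared, against 1348 DMSO peaks.

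**Figure D1:**
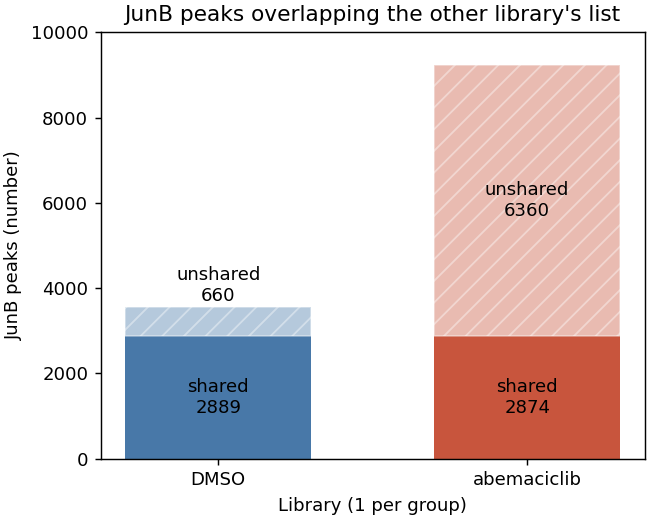
Number of JunB peaks (y axis) in the DMSO and the abemaciclib library (x axis, 1 library each). Solid parts are peaks that overlap the other list by at least 1 bp, 2889 and 2874, and hatched parts are peaks that do not, 660 and 6360.

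The strongest JunB sites by −log10 p were common to both libraries. All of the 100 strongest peaks of either list, ranked by −log10 p, overlapped a peak of the other list (interval 96.4 to 100%). Among the 1000 strongest, 98.5% (97.5 to 99.2%) of the DMSO peaks and 92.0% (90.1 to 93.6%) of the abemaciclib peaks did so. Among the 3000 strongest, the shares were 86.3% (85.0 to 87.5%) and 67.3% (65.6 to 68.9%). In a ranking by fold, the highest unshared peak had rank 99 in the abemaciclib list and rank 319 in the DMSO list. The shared peaks with the best mean rank included a pair of sites in 8q22.3. The first lay at chromosome 8, 103665883 to 103666503 in the DMSO list, with a fold enrichment of 35.6 (rank 9), and was the peak of highest fold in the abemaciclib list, at 77.1. The second, at chromosome 8, 103818475 to 103819692, had a fold of 42.3 in the DMSO list and 56.7 in the abemaciclib list. The 3 others were in 8q24.13 (chromosome 8, 126441783 to 126443734), 2q14.3 (chromosome 2, 128165030 to 128166323) and 10q22.3 (chromosome 10, 80732516 to 80733928). Their folds in the DMSO list were 35.4, 45.2 and 31.3, and in the abemaciclib list 60.4, 48.6 and 58.6. Folds of both lists rest on different backgrounds and are not a change in binding. In the order given, these sites held 237, 352, 555, 162 and 180 reads in DMSO. In abemaciclib they held 426, 446, 660, 167 and 236, before depth adjustment. Backgrounds were 3.77, 4.87, 9.73, 1.73 and 3.17 times the floor in DMSO, and 2.47, 3.75, 5.41, 1.34 and 1.66 times in abemaciclib.

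**Figure D2:**
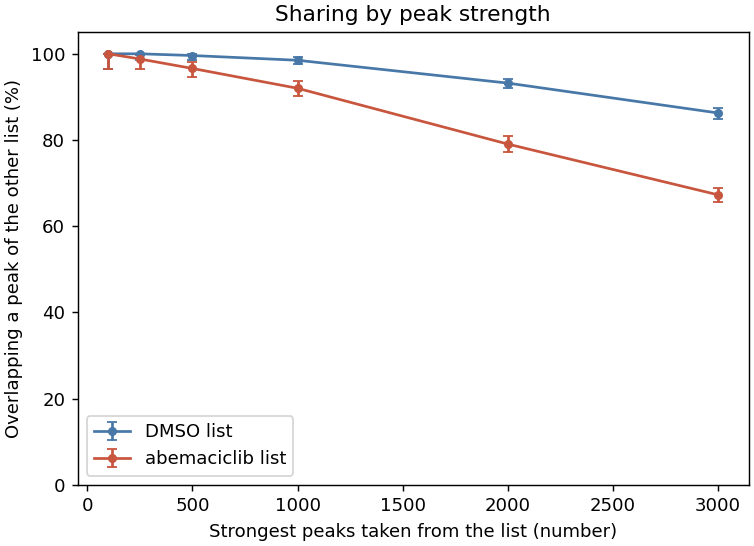
Share of peaks that overlap a peak of the other list (y axis, percent) against the number of strongest peaks taken from each list by −log10 p (x axis), with bars for the exact 95% interval. The share stays at 98.5% for the 1000 strongest DMSO peaks and is 92.0% for the 1000 strongest abemaciclib peaks.

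Unshared peaks were weaker than shared peaks within each list. In the abemaciclib list the median fold was 4.94 (quartiles 4.06 and 6.17) for unshared and 8.58 (6.15 and 12.2) for shared peaks. In the DMSO list it was 4.78 (4.08 and 5.65) for unshared and 6.45 (4.91 and 9.18) for shared peaks. Unshared peaks also included sites well supported in their own list, since 1539 of the 6360 abemaciclib-only peaks and 91 of the 660 DMSO-only peaks had a −log10 q of at least 10. A peak without a partner is not a shown gain or loss of binding, because reads of the other library at its position were not used here. The highest fold of an unshared peak was 25.7 in the abemaciclib list and 12.8 in the DMSO list. These 2 peaks held 72 and 39 reads before depth adjustment, on backgrounds of 1.00 and 1.41 times the floor, so their folds are not directly comparable.

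The abemaciclib-only peak of highest fold, 25.7 with a −log10 q of 82.3, lay in 14q32.12 at chromosome 14, 94425371 to 94426266. The next was in 6p21.2 at chromosome 6, 36647259 to 36648609, with a fold of 24.3 and a −log10 q of 76.0. A weak DMSO peak with a fold of 4.56 lay 40 bp from its edge. That DMSO peak ended at 36647218, while the abemaciclib summit lay at 36648314. The DMSO library thus had signal beside this site, and whether it had any at the summit is not known. The third was in 9q33.2 at chromosome 9, 124049149 to 124049954, with a fold of 21.2 and a −log10 q of 85.1. In 22q13.1 a peak at chromosome 22, 39380796 to 39381485, had a fold of 18.8, and in 2q37.3 a peak at chromosome 2, 242786129 to 242786719, had a fold of 18.3. The remaining 5 of the 10 named abemaciclib-only peaks lay in 19q13.33, 22q13.33, 3p25.3, 10p12.31 and 10q22.1, with folds between 16.9 and 18.0. These 10 peaks ranked between 99 and 305 by fold in their list.

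The DMSO-only peak of highest fold, 12.8 with a −log10 q of 31.3, lay in 4q22.3 at chromosome 4, 98510888 to 98511582. It was followed by a peak in 5p14.2 at chromosome 5, 23494525 to 23495146, with a fold of 11.9, and one in 10q21.1 at chromosome 10, 54168896 to 54169349, with a fold of 11.8. The other 2 named DMSO-only peaks lay in 11q21 at chromosome 11, 93719807 to 93720369, with a fold of 11.3, and in 21q22.3 at chromosome 21, 47563850 to 47564244, with a fold of 10.2. Ranks by fold of these 5 peaks were between 319 and 572 in the DMSO list. Genes near these sites, their position in promoters, exons or introns, and binding motifs were not analysed here.

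The larger number of peaks in the abemaciclib list was seen across the genome. All 40 chromosome arms with at least 50 abemaciclib peaks had more abemaciclib than DMSO peaks, with ratios from 1.81 on 19p to 3.78 on 16q. Peak density was highest on 20q, at 3.15 per Mb in the DMSO list and 9.80 per Mb in the abemaciclib list, followed by 17q, at 2.80 and 8.22 per Mb. The genome-wide values were 1.15 and 2.98 per Mb. The arms 1q, 17q and 20q, which were picked after the values were seen and are known to carry gains in MCF7 cells, held 13.4% of the DMSO peaks and 14.8% of the abemaciclib peaks on 7.01% of the genome's length. Among the 29 bands with at least 40 abemaciclib peaks, the ratio was highest in 16q24.3, with 7 DMSO and 44 abemaciclib peaks, 14q32.33, with 7 and 40, and 17q25.3, with 19 and 97. These bands lie at chromosome ends, but 19p13.3, also at an end, had a ratio of 2.07, with 30 and 62 peaks. Ratios of bands with fewer peaks rest on small counts and are not compared.

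**Figure D3:**
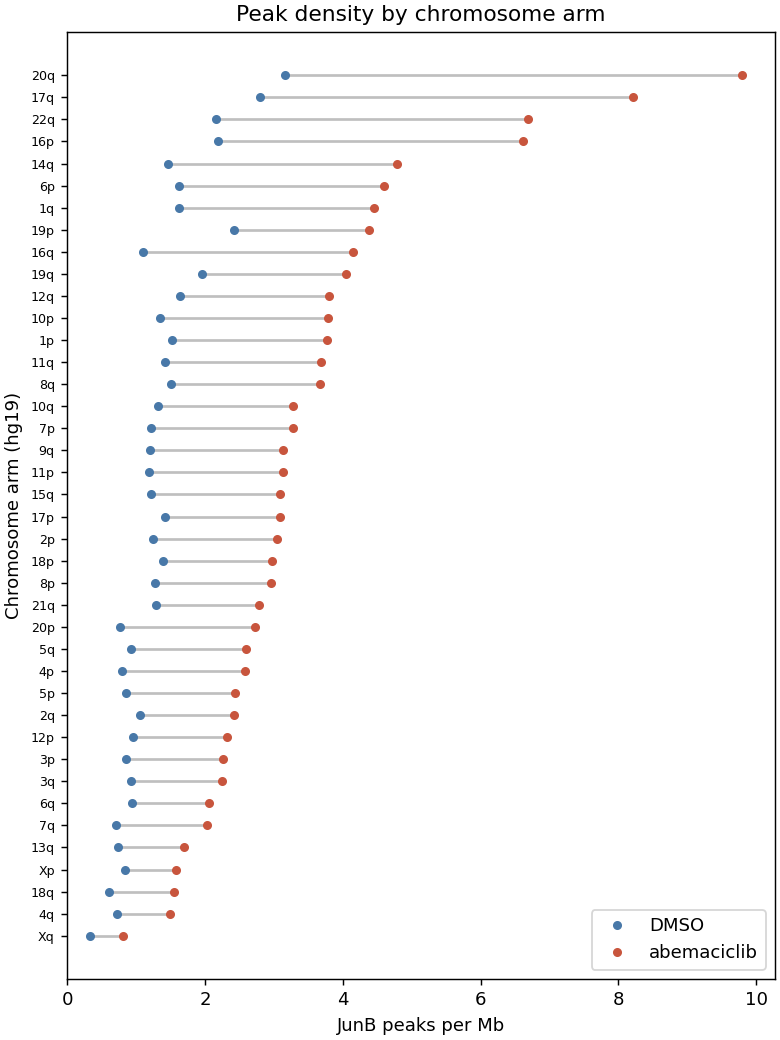
JunB peaks per Mb (x axis) on each chromosome arm with at least 50 abemaciclib peaks (y axis, hg19), with 1 point per library and a line joining both. The abemaciclib point lies to the right of the DMSO point on all 40 arms, and 20q has the highest density in both lists, 3.15 and 9.80 per Mb.

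Peaks of both libraries lay mostly in bands that stay light in Giemsa staining, which are on the whole rich in genes. Unstained bands held 59.1% (57.5 to 60.7%) of the DMSO peaks and 61.6% (60.6 to 62.6%) of the abemaciclib peaks on 42.2% of the length. The darkest bands, on 16.1% of the length, held 8.82% (7.91 to 9.80%) of the DMSO peaks and 6.82% (6.32 to 7.36%) of the abemaciclib peaks. Of the DMSO peaks in the darkest bands, 31.0% (25.9 to 36.4%) had no abemaciclib partner, against 16.0% (14.5 to 17.7%) in unstained bands. For abemaciclib peaks the unshared shares were 65.7% (61.9 to 69.4%) in the darkest and 69.2% (68.0 to 70.4%) in unstained bands.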

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

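Both tests in this part were chosen after the result was seen. The background that the peak caller assigned to each peak, a value outside the comparisons above, was high in 4 bands. Among bands with at least 20 abemaciclib peaks, these had a median background of at least 5 times the floor in both lists. In 17q23.2 it was 26.9 times the floor in the DMSO list and 16.7 times in the abemaciclib list, in 20q13.2 it was 26.7 and 20.9, in 20q13.13 it was 7.86 and 5.60, and in 3p14.1 it was 8.50 and 10.3. The DMSO value in 3p14.1 rests on 7 peaks only. The genome-wide medians were 1.79 and 1.35. Peaks in these bands had high pileups (medians of 82 and 70 reads, against 22 and 20 elsewhere) but low folds (3.65 and 3.81, against 6.0 and 5.62). A ranking by −log10 p placed 8 DMSO and 15 abemaciclib peaks of these bands among the top 50 of their lists, and a ranking by fold placed 0.

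Isolated artefact sites would leave the neighbouring bands at the usual background. In the 6 bands next to these 4, 51.2% (42.0 to 60.4%) of the abemaciclib peaks and 61.2% (46.2 to 74.8%) of the DMSO peaks had a background of at least 3 times the floor, against 4.62% and 12.7% in the remaining bands, which argues against single sites. A regional gain in copy number, known for 17q and 20q in MCF7 cells, could raise reads over whole bands in both libraries. The correlation used the 75 bands with at least 10 DMSO and 20 abemaciclib peaks, and 3p14.1 was not among them. Across these bands the median backgrounds of both lists went together (Spearman rho 0.83 across bands, which are not replicates). Without the high-background bands among them, rho was 0.81. Such a correlation would hold for any regional feature seen by the control or controls. Copy number was not measured, so the gain remains a hypothesis.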

How the results depend on the processing

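The abemaciclib list was the longer one under every threshold and region filter run, with ratios from 2.23 to 2.60. Leaving out bands of high background or chromosome ends, and thinning the abemaciclib pileups and backgrounds by the ratio of the background floors (8674.5 peaks left, 32.8% of them shared), with or without a raised background, were alternatives chosen after seeing the data. The excess of abemaciclib-only over DMSO-only peaks held under each definition of sharing run, but nearly vanished with lists of equal length, by construction. No result reversed. Peak counts and their ratios were taken as kept within a factor of 1.5, and shares and strength ratios within the 95% interval of the value reported, so that a small shift of a share can count as moved and a larger one of a count as kept. By these limits 50 values were kept and 28 moved. Some of those kept could hardly move. No intervals overlapped or abutted within a list, so merging could not change the counts, and leaving out the Y chromosome dropped 1 peak. Named peaks without any overlap could not gain a partner under a reciprocal overlap of 50%.

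At a −log10 q of at least 10, 1698 DMSO and 3788 abemaciclib peaks were left, the shared shares were 86.9% and 38.8%, and 2318 abemaciclib-only and 222 DMSO-only peaks remained. At a −log10 q of at least 5 in both lists the shares were 84.6% and 35.4%, with 427 DMSO-only peaks. A reciprocal overlap of 50% gave 71.8% and 27.6% with 1000 DMSO-only peaks, and summits within 100 bp gave 66.5% and 25.5% with 1190. Thinning with the raised background gave 79.3% and 34.6%. Peaks within 1 kb gave 32.1% of abemaciclib peaks shared. Lists of equal length gave 62.0% and 61.5%, with 1365 abemaciclib-only and 1348 DMSO-only peaks. The ratio of shared to unshared median strength was 1.35 by fold in the DMSO list, 1.76 by −log10 p and 1.25 at a −log10 q of at least 5. In the abemaciclib list it was 1.74, 2.49 and 1.54. By covered length, 16.4% of the abemaciclib list lay on 1q, 17q and 20q. By construction, stricter thresholds leave fewer peaks, and narrower definitions of sharing give lower shares and more unshared peaks. For the other shifts the cause was not tested.

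Of the 10 named abemaciclib-only peaks, 9 had no DMSO peak within 1 kb. Alternatives for promoter distance, motif windows and gene list distance were not run. Leaving out a library was not possible, and no paired analysis was possible because each group has 1 library. Weak sites are limited by depth, since the median summit held 23 and 20 reads.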

Other observations

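Most tests in this part were chosen after the result was seen. The exceptions are the tests of the darkest bands at a stricter threshold and of background floors at chromosome ends. At shared sites, pileups were compared between the libraries after division by the background floor of each. Across 2870 one-to-one pairs the median ratio of abemaciclib to DMSO was 0.04 on the log2 scale (bootstrap interval 0.02 to 0.05), with 98 pairs at least 2 times higher in the abemaciclib library and 58 in the DMSO library. Among 327 pairs with a mean pileup of at least 60 reads, the SD of the log2 ratio was 0.49, against 0.22 from counting alone. The largest differences toward abemaciclib, chosen after their values were seen, were in 22q13.33 at chromosome 22, 50720932 to 50721292, with 22 reads in DMSO and 119 in abemaciclib (4.44-fold after depth adjustment), and in 12q24.33 at chromosome 12, 133100974 to 133101298, with 14 and 70 reads (4.11-fold). The largest toward DMSO were in 5q21.3 at chromosome 5, 104952249 to 104952811, with 38 and 15 reads (3.08-fold), and in 7p22.1 at chromosome 7, 6277771 to 6278413, with 69 and 28 reads (3.0-fold). Spread between cultures is unknown.

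Unshared peaks of both lists lay nearer to peaks of the other list than chance placement gives. Of the abemaciclib-only peaks, 26.7% had a DMSO summit within 50 kb, against 10.9 ± 0.38% (SD over 100 random placements), 2.46 times as many. Of the DMSO-only peaks, 38.0% had an abemaciclib summit within 50 kb, against 21.6 ± 1.3%, 1.76 times as many. The random positions ignore gene density and unmappable sequence, and the cause of the excess was not tested. There were 72 clusters of at least 3 abemaciclib-only peaks with neighbouring summits within 10 kb of each other, against 4.31 ± 2.03 (SD) over 100 random placements with the same limits. The 4 largest, of 5 peaks each, lay in 20q13.33, 17q25.3 and 16p13.3, the last with 2 of them, and the cluster in 17q25.3 also held 1 DMSO peak.

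The abemaciclib list was 2.60 times as long as the DMSO list. Sequencing depth alone is argued against, since thinning to the DMSO background floor left a ratio of 2.44. A uniform gain in enrichment would need a factor of 2.00, while shared pairs among the 500 strongest peaks of the DMSO and abemaciclib lists gave 0.91 (0.88 to 0.94) and 1.18 (1.13 to 1.22), each shifted toward the list used for selection. The caller's background at shared sites, divided by the floor of its list, was 1.24 times higher in DMSO. Applying that factor after thinning left a ratio of 2.27, or 1.81 together with the highest bound on enrichment. The factor comes from shared sites only. The DMSO background at abemaciclib-only sites is not known, so a larger difference there is not excluded. In 160 shared pairs with summits within 3 bp, the background over the floor was equal within 1% in 2.5% of pairs. The control or controls are not named, so whether both lists used the same control is not known. An effect of abemaciclib may account for the remaining excess of peaks, but so might variation between cultures, a loss of weak sites only, or an unmatched control, none of which 1 library per group can tell apart.

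Darkest bands, on 16.1% of the length, held 14.7% (12.1 to 17.6%) of DMSO-only and 6.51% (5.92 to 7.14%) of abemaciclib-only peaks, against 7.48% of shared DMSO peaks. The 2 Mb at chromosome ends, on 3.10% of the length, held 2.88% (1.74 to 4.46%) and 8.35% (7.68 to 9.06%), against 5.54%, so that both intervals of the DMSO-only peaks include the share by length. Unstained bands, on 42.2% of the length, held 50.9% (47.0 to 54.8%) of the DMSO-only peaks, an interval above the share by length. Weak calls near the threshold are argued against for the darkest bands, with 19.8% (12.2 to 29.4%, 18 of 91 peaks) against 6.69% (5.50 to 8.06%) at a −log10 q of at least 10. The first of these intervals includes the 16.1% share by length, and the same q threshold is not an equal stringency in both lists. Unreliable DMSO-only calls in general are therefore not excluded. At the ends the shares were 3.30% (0.69 to 9.33%, 3 of 91 peaks) and 6.24% (5.08 to 7.56%) at that threshold, and 1.80% (0.66 to 3.87%) and 6.56% (5.81 to 7.38%) at a −log10 q of at least 5. At a −log10 q of at least 10 the ends held 5.85% (4.75 to 7.11%) of shared DMSO peaks. They held 5.74% (4.81 to 6.78%) of shared abemaciclib peaks. At that threshold an excess of abemaciclib-only over shared peaks at the ends was not seen beyond counting error. Low background at the ends may contribute, as 26.2% (22.5 to 30.1%) of abemaciclib-only peaks there were at the floor against 19.3% (18.3 to 20.3%) elsewhere. Shared and DMSO-only peaks at the ends were not compared in this way. Whether low background accounts for any of the excess among all peaks was therefore not tested. Base composition bias cannot be told apart from treatment, because the median log2 ratio at shared sites was 0.094 higher in unstained than in darkest bands with an interval of 0.02 to 0.20, and sequence was not measured.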
